A study of Homo sapiens with 12 samples.

How the data were processed

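Total RNA came from HEK-293TO cells depleted for 72 h by reverse transfection of siRNAs, in 4 groups of 3 libraries. Per the labels' protocols, ribosomal RNA was removed with Ribo-Zero and libraries were made with a TruSeq RNA kit, for paired-end sequencing. The submitters' processing notes name TopHat2, DESeq2 and the genome build hg19, without versions. The counting tool, its strand setting and the annotation version are not given in the sources used here. The samples of the control and UPF1 groups carry a pointer to another record, and those of the hnRNP L and double groups do not. A difference in date or batch between these pairs of groups would coincide with the hnRNP L siRNA and could not be told apart from it.

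The deposited table has 10452 rows, 1 coding RefSeq transcript each, with a gene symbol and a 3′ UTR length. The authors deposited whole-number read counts per library, and every row has at least 25 counts in every library. A transcript below that level in any library would be missing, so strong falls of weakly expressed transcripts cannot be seen. Rises of transcripts that lie below that level in control cells cannot be seen either. The authors also deposited RPKM values per library, per the file headers, of which 1 cell holds text. Per the file headers the authors give a further expression signal per library, called NE, whose definition is not stated and which was not tested. The authors deposited log2 fold changes and adjusted p-values for 3 comparisons, made with DESeq2 per the submitters' processing notes, and marks for transcripts called down and rescued. In the gene symbols, 18 had been turned into dates and 11 were listed more than once, so the latter were kept apart by transcript identifier. HNRNPL and UPF1 are not analysed here.

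Counts were tested with edgeR 4.0.16 in R 4.3.3. One model with a mean per group was fitted to all 12 libraries, with TMM factors (0.978 to 1.019), so that all groups shared one estimate of the spread with 8 residual degrees of freedom. Dispersions were estimated and contrasts tested with glmQLFit and glmQLFTest. The filter for low counts (filterByExpr) removed 0 transcripts. P-values were adjusted by the Benjamini-Hochberg method over 10452 transcripts, with a threshold of 0.05. The comparisons were each knockdown against control, the double knockdown against each single one, and the interaction. Standard errors of log2 fold changes were taken as the fold change over the square root of its F statistic. Normalized counts are counts divided by TMM-scaled library size relative to the mean library, given as mean ± SD over 3 libraries. Changes are relative to the median transcript, since no spike-in was used here to fix an absolute scale.

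Depth was read as the sum of counts in the table, 6594833 to 11876302 per library. Library totals implied by the deposited RPKM values were 37557507 to 60919163, so the table held 16.5% to 20.6% of them. The 10 most counted transcripts took 2.63% to 3.47% of counts. No pair of libraries in a group agreed within sampling noise, as the lowest chi-square per degree of freedom was 1.45. The labels give no meaning to the replicate numbers. Deviations from the group means correlated above 0.1 in all 3 same-numbered pairs of the double with the UPF1 knockdown (0.154 to 0.54). The same held for its pairs with the hnRNP L knockdown (0.111 to 0.303). From the data alone, the numbers were therefore taken as a possible pairing in these 2 comparisons. The pairing is uncertain, since replicate 1 of the UPF1 knockdown correlated more with replicate 3 of the double (0.44) than with its replicate 1 (0.154). Unless a block is named, counts and p-values come from the fit without a block.

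Before the data were examined, 27 gene lists, the comparisons and the rule for naming genes were fixed. Lists with at least 5 measured members (23) were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation. Both settings were planned before the data were examined, and the calls of lists below are those at the preset one. Adjustment was over the lists of a comparison. The rotation test fry and 10000 random lists matched on expression were also run for each list but did not set the calls. The naming rule took HNRNPLL and BCL2 always and the 6 largest rises and falls among transcripts past the threshold with a mean of at least 100 normalized counts. For the interaction it took the 4 largest each way. From each list described it took the 2 members with the smallest adjusted p in each direction. Other genes in the text were chosen after their values were seen: those that complete a count of 6 or fewer members, LAMC1 on UPF1 knockdown alone, and the genes with opposing interactions.

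Transcripts were matched by their RefSeq identifiers, and among several matches by the nearest 3′ UTR length, to GENCODE release 29, an annotation of another genome build than the authors' hg19, so no coordinates are given. A match was found for 10195 rows (97.5%). For CA motifs, the first 400 nt after the stop codon were read in 6303 transcripts whose annotated 3′ UTR was at least 100 nt long and within 10 nt of the deposited length. Transcripts that fell or rose on hnRNP L knockdown were set beside 1000 random sets matched on mean expression in 20 bins.

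The analysis was tested on simulated data in which 200 of 10452 transcripts were changed. For hnRNP L knockdown against control, 20 of 50 transcripts changed 1.3-fold were recovered, as were 44 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold. Of 10252 unchanged transcripts 14 were called. For the interaction the numbers were 14, 21, 48 and 50 of 50, with 8 unchanged transcripts called. A planted trend with GC content in 1 library gave a rho of 0.753 without and 0.001 with the GC correction.

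Alternatives were other size factors, DESeq2 1.42.0, no filter, other thresholds, a minimum fold change, only the groups compared, the replicate number as a block, other list settings and leaving out each library. A GC correction (lowess of each library's deviation on transcript GC content, span 0.3), a latent factor, RPKM-implied totals, values without replicate 2 of the UPF1 knockdown for lists, correlations and comparisons that do not use it, and blocked fits with a GC correction or of lists were added after seeing the data. The GC correction also removes any true response that follows GC content. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.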

Results

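Total RNA was sequenced from HEK-293TO cells, a human embryonic kidney line, 72 h after transfection with small interfering RNAs (siRNAs). The 12 libraries formed 4 groups of 3. They received a non-specific siRNA (control), an siRNA against hnRNP L, an siRNA against UPF1, or both targeting siRNAs (double knockdown). The hnRNP L protein binds CA-rich RNA, and UPF1 is an RNA helicase required for nonsense-mediated mRNA decay (NMD). The series title poses the question as one of protection of mRNAs from NMD by hnRNP L. The design is therefore a 2 by 2 layout in which the effect of each knockdown can be read with and without the other one. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values below therefore measure the spread between these libraries, which could be technical.

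The table held 10452 coding transcripts, 1 per row, each with at least 25 reads in every library. Reads in the table ranged from 6594833 to 11876302 per library. The targeted genes, HNRNPL and UPF1, are not analysed here, so the labels were not checked against the depletion of either target. The first principal component carried 68.2% of the variance and separated the 6 UPF1-depleted libraries from the other 6. The second carried 13.8% and separated the libraries by hnRNP L siRNA. Within groups, log counts correlated at 0.978 to 0.996. Replicate 2 of the UPF1 knockdown stood farthest from its group, with a score of 0.70 on the main axis of within-group deviations against −0.36 to 0.27 for the others.

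**Figure D1:**
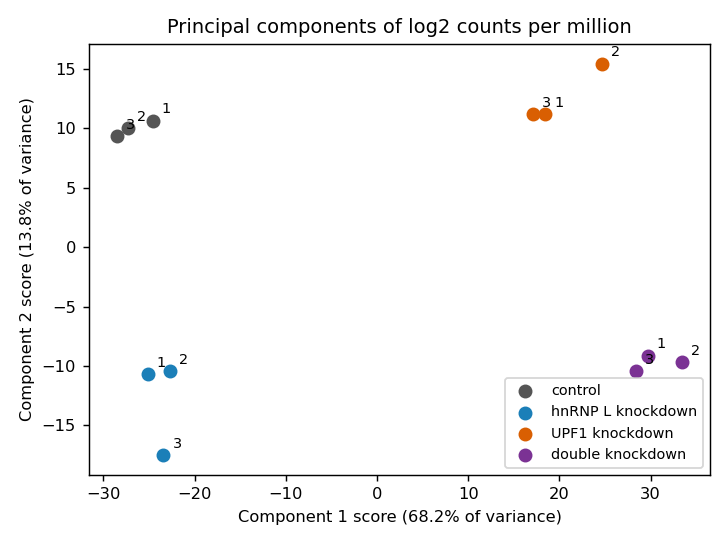
Scores of the 12 libraries on the first (68.2% of variance) and second (13.8%) principal components of log2 CPM, coloured by group, with the replicate number beside each point. The 6 UPF1-depleted libraries lie at positive and the other 6 at negative scores on the first component, and the hnRNP L-depleted libraries lie at negative scores on the second.

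Knockdown of hnRNP L lowered 1019 transcripts and raised 978 at an adjusted p under 0.05 (edgeR quasi-likelihood test, 10452 tested, 3 libraries per group). The strongest fall was that of INPP5D (NM_001017915), which encodes an inositol 5-phosphatase of phosphoinositide signalling. It went from 267 ± 26.7 normalized counts (SD, n = 3) in control cells to 71.7 ± 26.6 (log2 fold change −1.85, SE 0.18, adjusted p = 2.23e-05). FARP1, a guanine nucleotide exchange factor, fell from 490 ± 23.5 to 145 ± 16.2 (−1.75, SE 0.10, adjusted p = 4.4e-07). Falls of 2.33- to 2.52-fold followed in PTPRB, a receptor tyrosine phosphatase, ETV5, an ETS transcription factor, FAM26E and ZNF404. The strongest rises were 2.61-fold in the zinc finger gene ZNF586, 2.58-fold in SLC35G1 and 2.46-fold in SYP, which encodes the synaptic vesicle protein synaptophysin. PPAPDC1B, IQCH and THAP2 rose 2.11- to 2.23-fold. Most changes were smaller, since 8 transcripts rose and 31 fell by at least 2-fold. HNRNPLL, the paralog of HNRNPL, rose from 447 ± 12.6 to 566 ± 6.91 normalized counts (log2 fold change 0.34, SE 0.069, adjusted p = 0.00399). BCL2, an apoptosis inhibitor, fell from 258 ± 19.5 to 171 ± 20.1 (−0.58, SE 0.10, adjusted p = 0.00148).

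Other RNA-processing genes moved with hnRNP L knockdown. PTBP2, the neuronal paralog of the splicing regulator PTBP1, fell by 1.01 on the log2 scale (SE 0.11, adjusted p = 4.03e-05). XRN2, the nuclear 5′ to 3′ exoribonuclease, fell by 0.80 (SE 0.069, adjusted p = 1.02e-05). The splicing factor genes SRSF6 and SRSF7 rose by 0.37 and 0.30, and SRSF4 fell by 0.26. The proapoptotic BID fell by 0.59 (SE 0.087, adjusted p = 0.000518). The lists behind these genes did not pass by camera. Of 25 other hnRNP genes 2 rose and 1 fell (camera adjusted p = 0.597), and of 33 mRNA decay enzymes 4 rose and 1 fell (0.275). Of 13 SR protein genes 3 rose and 1 fell (0.272), and of 15 BCL2 family genes 0 rose and 4 fell (0.0835). By fry, which does not set a list against other transcripts, the decay enzymes and the BCL2 family passed (adjusted p = 0.0121 and 0.00804). The hnRNP and SR protein genes did not (fry adjusted p = 0.421 and 0.0696). The counts were the same for the hnRNP, decay enzyme and BCL2 lists adjusted over the list alone, and 3 and 2 for the SR proteins.

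Among the 23 gene lists tested, 5 were higher and 2 were lower on hnRNP L knockdown relative to the other transcripts. Of 9 neuronal genes, 5 rose and 0 fell (camera adjusted p = 0.000901, and adjusted p = 0.17 with an estimated correlation). They were SYP, TUBB3, and the neurofilament and intermediate filament genes NEFL, NEFH and INA, and TUBB3 rose by 0.56 on the log2 scale. Among 26 p53 target genes, 8 fell and 0 rose (adjusted p = 0.000575, and adjusted p = 0.17 with an estimated correlation). BTG2, an antiproliferative gene, fell by 0.35, and POLH, a translesion DNA polymerase gene, fell by 0.32. Of 33 genes of the integrated stress response and its transcription factor ATF4, 8 rose and 0 fell (adjusted p = 0.00268, and adjusted p = 0.424 with an estimated correlation). ATF4 rose by 0.44 and ASNS, encoding asparagine synthetase, by 0.42. Ribosomal protein genes rose in 11 of 72 cases and fell in 0 (adjusted p = 1.41e-05, and adjusted p = 0.424 with an estimated correlation), with RPS6 at 0.40 and RPL6 at 0.30. Cytosolic heat shock genes rose in 4 of 14 cases and fell in 0 (adjusted p = 0.00149, and adjusted p = 0.191 with an estimated correlation), namely HSPA1A, HSPA1B, HSPA8 and DNAJB1. HSPA1A rose by 0.50 and HSPA1B by 0.48, but these near-identical genes share reads and their separate values are uncertain. Replication-dependent histone genes rose in 4 of 22 cases and fell in 1, HIST1H1D (adjusted p = 0.00125, and adjusted p = 0.635 with an estimated correlation). The 4 were HIST3H2BB, HIST1H2BD, HIST1H2BK and HIST2H2BF, which also have close copies. Extracellular matrix and mesenchymal genes fell in 8 of 20 cases and rose in 2 (adjusted p = 0.027, and adjusted p = 0.17 with an estimated correlation). FN1, encoding fibronectin, fell by 0.47 and COL6A1 by 0.56, while VIM, encoding vimentin, rose by 0.49 and ITGB1 by 0.35. Adjusted over the list alone, the numbers that rose and fell were 5 and 0 for neuronal, 0 and 10 for p53, 9 and 1 for stress response, 11 and 0 for ribosomal, 6 and 0 for heat shock, 7 and 1 for histone, and 3 and 9 for matrix genes. The matrix call ended when transcripts below a mean of 100 normalized counts were left out (adjusted p = 0.0561).

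The number of calls for hnRNP L knockdown depended on the libraries used. It was lower without any of the 6 libraries compared, from 1112 (without replicate 3 of the hnRNP L knockdown) to 1469 (without its replicate 1). No called transcript changed sign in these fits. Leaving out the divergent replicate 2 of the UPF1 knockdown, which adds to the shared estimate of the spread, gave 3305. A fit to the 6 libraries compared called 3241, a fit with a correction for GC content 3611, and one with the library totals implied by the authors' RPKM values 1239.

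**Figure D2:**
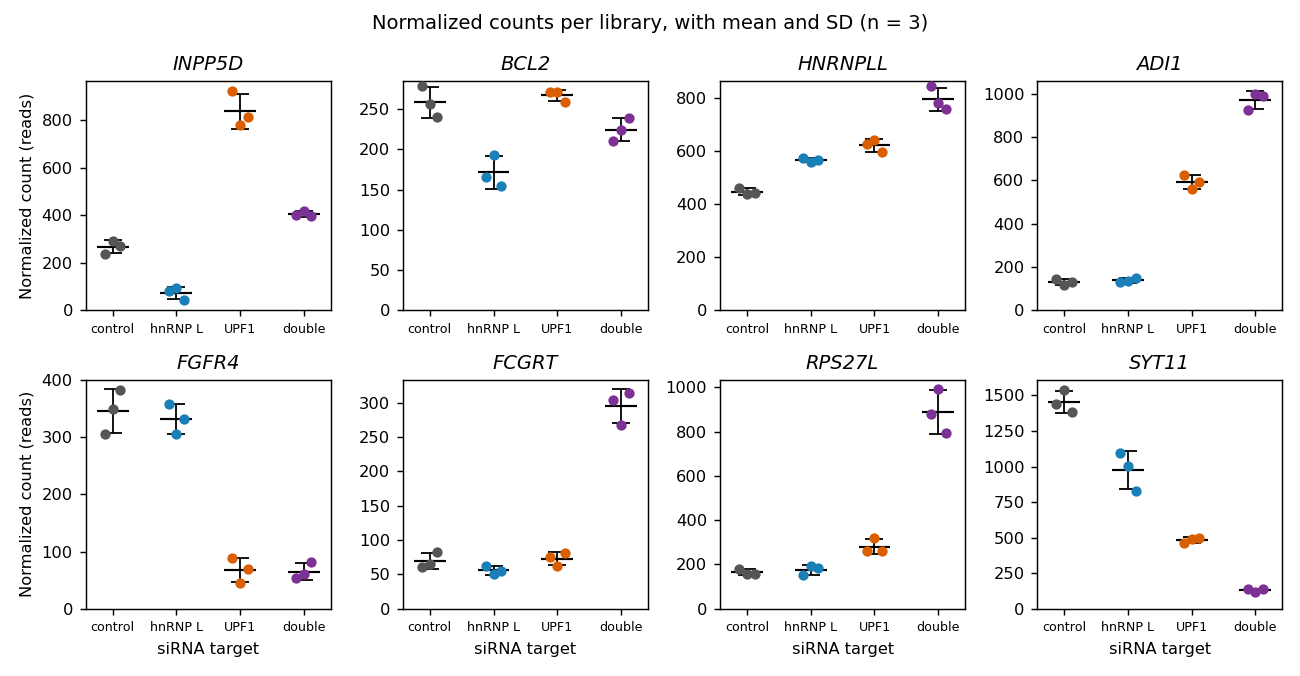
Normalized counts (reads) of 8 named genes in each of the 12 libraries, by siRNA target, where points are libraries, horizontal bars are means and error bars are SDs (n = 3). INPP5D fell from 267 to 71.7 on hnRNP L knockdown and stood at 839 on UPF1 knockdown, and FCGRT reached 296 in the double knockdown against 69.4, 55.7 and 72.8 in the other groups.

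Knockdown of UPF1 moved 54.5% of transcripts. In all 2995 rose and 2706 fell, and 242 rose and 250 fell by at least 2-fold. ADI1 (NM_018269), an enzyme of the methionine salvage pathway, rose from 130 ± 13.9 to 593 ± 32.6 normalized counts (log2 fold change 2.19, SE 0.093, adjusted p = 8.68e-10, edgeR). ACTA2, a smooth muscle actin gene whose sequence is close to those of other actins, rose 4.31-fold. HSBP1L1, ZNF528, ULBP1, a ligand of the NKG2D receptor, and ZNF606 rose 3.97- to 4.15-fold. FGFR4 (NM_213647), a fibroblast growth factor receptor gene, fell from 346 ± 38.2 to 67.7 ± 21.1 (−2.35, SE 0.18, adjusted p = 8.23e-08). SLCO4A1, TUBB3, STC1, encoding the secreted glycoprotein stanniocalcin, BCAM and CILP2 fell 3.66- to 4.11-fold. HNRNPLL rose from 447 ± 12.6 to 622 ± 24.3 (0.48, SE 0.069, adjusted p = 4.03e-05). BCL2 had a log2 fold change of 0.05 (SE 0.097, adjusted p = 0.702), smaller than the spread between libraries.

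Genes of the NMD pathway and its reporters rose on UPF1 knockdown. Of 24 transcripts in wide use as endogenous NMD reporters, 15 were measured. Of these 15, 11 rose and 0 fell (camera adjusted p = 5.92e-05, and adjusted p = 0.0569 with an estimated correlation). ATF4 rose by 1.19 on the log2 scale and the stress-induced factor ATF3 by 0.79. Of 9 NMD factor genes, 6 rose and 0 fell (adjusted p = 0.00618, and adjusted p = 0.0569 with an estimated correlation), namely UPF2, SMG1, SMG5, SMG6, SMG9 and NBAS. UPF2 rose by 0.88 and SMG6 by 0.70. The 2 lists share 5 genes, so they are not separate evidence. Stress response genes rose in 21 of 33 cases and fell in 1, SHMT2 (adjusted p = 8.18e-06, and adjusted p = 0.163 with an estimated correlation). SLC7A11, the cystine transporter gene, rose by 1.5. Endoplasmic reticulum chaperone and unfolded protein response genes rose in 13 of 22 cases and fell in 1 (adjusted p = 0.044, and adjusted p = 0.163 with an estimated correlation). EDEM1 and SEL1L, genes of endoplasmic reticulum-associated degradation, rose by 0.61 and 0.64, and the chaperone gene HYOU1 fell by 1.3. This call ended when transcripts below a mean of 100 normalized counts were left out (adjusted p = 0.0545). Among p53 targets 21 of 26 rose and 1, BAX, fell (adjusted p = 1.04e-05, and adjusted p = 0.0461 with an estimated correlation). TNFRSF10B, a death receptor gene, rose by 1.04 and TP53I3 by 1.87. Each of these 5 counts was the same adjusted over the list alone.

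On UPF1 knockdown 7 lists were lower at the preset correlation. Of 28 S-phase genes, 17 fell and 2, TYMS and GINS4, rose (camera adjusted p = 0.000258, and adjusted p = 0.0367 with an estimated correlation). MCM3 and MCM4, subunits of the replicative helicase, fell by 0.63 and 0.64. Of 21 sterol synthesis and uptake genes, 12 fell and 2 rose (adjusted p = 0.000128, and adjusted p = 0.0367 with an estimated correlation). SQLE, encoding squalene epoxidase, fell by 1.3 and IDI1 by 1.39, and PMVK and STARD4 rose by 0.98 and 0.37. Heat shock genes fell in 9 of 14 cases and rose in 1, DNAJB4 (adjusted p = 3.13e-05, and adjusted p = 0.0569 with an estimated correlation). HSPA1A and HSPA1B both had a log2 fold change of −1.36, with the read sharing named above. Glycolytic genes fell in 10 of 15 cases and rose in 1, the glucose transporter gene SLC2A3 (adjusted p = 0.00544, and adjusted p = 0.257 with an estimated correlation). ALDOC fell by 1.38 and HK2 by 1.02. Nuclear genes of oxidative phosphorylation fell in 22 of 60 cases and rose in 5 (adjusted p = 0.00829, and adjusted p = 0.694 with an estimated correlation), with COX8A at −1.20 and NDUFS5 at −1.12. The 5 were NDUFA1, NDUFB1, NDUFB5, SDHC and ATP5F1. That call ended without replicate 2 of the UPF1 knockdown (adjusted p = 0.0553). Matrix genes fell in 11 of 20 cases and rose in 6 (adjusted p = 0.0293, and adjusted p = 0.0918 with an estimated correlation), and this call ended with a correction for GC content (adjusted p = 0.165). COL6A1 fell by 1.5 and CDH1, an epithelial cadherin gene that this list also holds, by 1.57, while VIM and ITGB1 rose by 0.96 and 0.79. The fall of the list is therefore not a measure of mesenchymal expression. When adjusted over the list alone, 10 heat shock genes fell, and the other 5 counts were the same.

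Of 14 genes in use as references, 7 fell and 1, YWHAZ, rose on UPF1 knockdown (camera adjusted p = 0.0271, and adjusted p = 0.126 with an estimated correlation), with the same counts adjusted over the list alone. GUSB fell by 1.43 and ACTB by 0.61. These directions are relative to the median transcript. With the library totals implied by the authors' RPKM values in place of TMM factors, the median of all transcripts rose by 0.117 and 67% of calls were higher, against 52.5%. The median of the oxidative phosphorylation list then moved from −0.115 to −0.008, and that of the reference genes from −0.235 to −0.13.

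**Figure D3:**
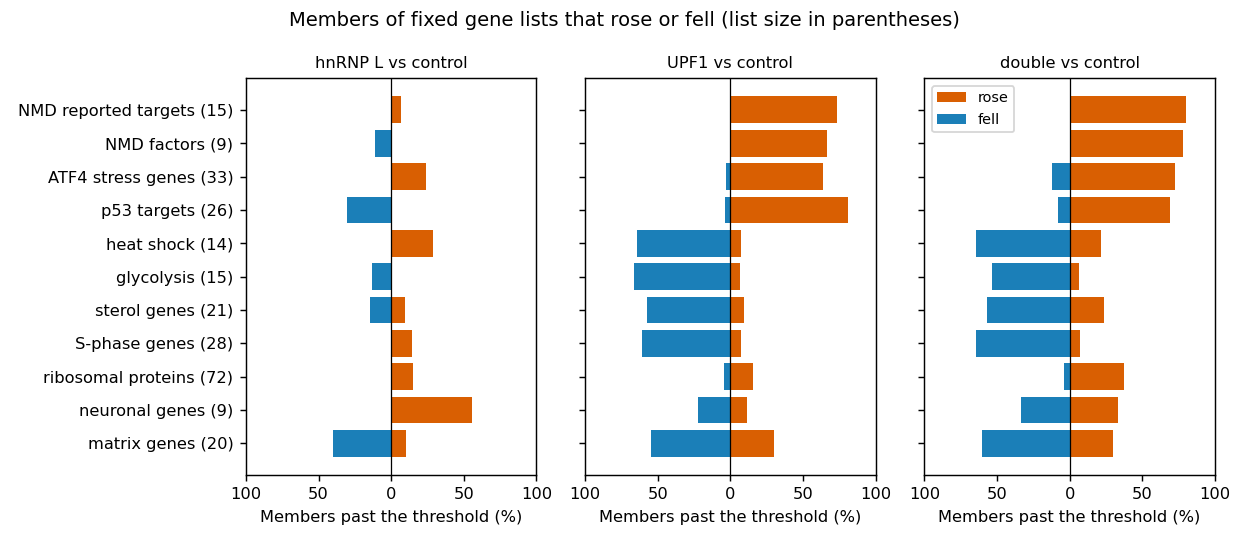
Percent of the measured members of 11 gene lists that rose (orange, right) or fell (blue, left) at an adjusted p under 0.05 against control in the hnRNP L, UPF1 and double knockdowns, with list sizes in parentheses. Of 26 p53 targets, 0 rose and 8 fell on hnRNP L knockdown, while 21 rose and 1 fell on UPF1 knockdown.

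The double knockdown differed from control in 6635 transcripts, of which 3335 rose and 3300 fell. At least 2-fold changes were seen in 472 that rose and 526 that fell. SYT11 (NM_152280), a synaptotagmin gene, fell from 1450 ± 79.2 to 129 ± 10.2 normalized counts (log2 fold change −3.50, SE 0.11, adjusted p = 2.95e-11, edgeR). SLC4A8, a sodium-coupled bicarbonate transporter gene, fell 8.09-fold from 753 ± 20.4 to 93.2 ± 5.44. HPSE, encoding heparanase, RAB39B, PCP4L1 and AATK fell 5.54- to 6.29-fold. ZNF528 rose 7.52-fold and ADI1 7.45-fold, from 130 ± 13.9 to 972 ± 42.1. DNAH17, REEP3, ZNF586 and RPS27L, which encodes a ribosomal protein S27-like protein, rose 5.36- to 6.54-fold. HNRNPLL rose by 0.83 (SE 0.068, adjusted p = 7.98e-08) to 795 ± 43.8. BCL2 had a log2 fold change of −0.21 (SE 0.098, adjusted p = 0.0751).

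In the double knockdown 6 lists were higher and 4 were lower than control. They were NMD reporters (12 rose and 0 fell of 15, camera adjusted p = 0.000485), NMD factors (7 and 0 of 9, 0.0205), stress response genes (24 and 4 of 33, 4.04e-06), unfolded protein response genes (14 and 1 of 22, 0.0119), p53 targets (18 and 2 of 26, 0.000798) and ribosomal protein genes (27 and 3 of 72, 0.0302). ATF4 rose by 1.57, SLC7A11 by 1.75, MDM2 by 1.08 and the NMD factor gene SMG5 by 1.32. S-phase genes were lower (2 rose and 18 fell of 28, adjusted p = 0.003), as were heat shock genes (3 and 9 of 14, 0.0205) and glycolytic genes (1 and 8 of 15, 0.00882). MCM6 fell by 0.85 and HK1, encoding a hexokinase, by 1.14. With an estimated correlation none of these 10 calls held, at an adjusted p of 0.107 for NMD reporters, NMD factors, unfolded protein response, p53 and S-phase genes, 0.202 for stress response, 0.215 for heat shock, 0.296 for glycolytic and 0.772 for ribosomal and oxidative phosphorylation genes. Oxidative phosphorylation genes rose in 7 and fell in 23 of 60 cases (adjusted p = 0.0349), and their median turned from −0.10 to 0.002 with RPKM-implied totals. Adjusted over the list alone, 24 ribosomal genes rose and 2 fell, 22 oxidative phosphorylation genes fell, 3 S-phase genes rose and 20 fell, 1 NMD factor gene fell, and the other counts were the same. RPKM-implied totals raised the median transcript by 0.1 and the share of higher calls from 50.3% to 61.7%.

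The effect of hnRNP L knockdown in UPF1-depleted cells was read from the double against the UPF1 knockdown, where 1004 transcripts rose and 1000 fell. FCGRT, encoding the neonatal Fc receptor, rose from 72.8 ± 9.7 to 296 ± 24.5 normalized counts (log2 fold change 2.01, SE 0.13, adjusted p = 1.9e-07, edgeR). ZNF586 rose 3.77-fold, RPS27L 3.2-fold, SYP 2.55-fold, MDFIC 2.54-fold and TTPAL 2.38-fold. SLC4A8 fell 4.71-fold and SYT11 3.75-fold. PCP4L1, HPSE, the laminin gene LAMC3 and CPT1C fell 2.75- to 3.6-fold. XRN2 fell by 0.68 and PTBP2 by 0.42. BCL2 had a log2 fold change of −0.26 (SE 0.097, adjusted p = 0.0766), and HNRNPLL rose by 0.36. Sterol genes rose in 8 of 21 cases and fell in 2, HSD17B7 and SREBF2 (camera adjusted p = 0.0036, and adjusted p = 0.0976 with an estimated correlation). INSIG1, the sterol-regulated retention factor of the SREBP pathway, rose by 1.14 and HMGCS1, encoding HMG-CoA synthase, by 0.80. Stress response genes (10 rose and 2 fell, adjusted p = 0.0475), unfolded protein response genes (7 and 0, 0.0475), histone genes (1, HIST3H2BB, and 0, 0.0317) and ribosomal protein genes (10 and 0, 0.000377) were also higher. None of these 4 held with an estimated correlation (adjusted p = 0.814, 0.457, 0.854 and 0.814) or without replicate 2 of the UPF1 knockdown (adjusted p = 0.339, 0.116, 0.597 and 0.0762). Adjusted over the list alone, 9 sterol, 12 stress response, 7 unfolded protein response, 1 histone and 6 ribosomal genes rose, and 2 sterol, 2 stress response and 1 unfolded protein response genes fell. The number of transcripts called was 3141 without replicate 2 of the UPF1 knockdown, 1330 without replicate 1 of the double knockdown, and 956 in a fit to the 6 libraries compared. It was 2575 with the replicate number as a block, 3696 with a GC correction, 3980 with the block beside that correction, and 1312 with RPKM-implied totals.

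The hnRNP L effects with and without UPF1 were then set side by side. Fold changes in the 2 comparisons, which share no library, correlated across transcripts at r = 0.597. Of the transcripts called, 438 were higher in both (93.9 for independent lists) and 458 were lower in both (97.5). Opposite calls numbered 18 lower then higher and 3 higher then lower, against 97.9 and 93.6 for independent lists. Transcripts are not independent replicates. A batch that coincides with the hnRNP L siRNA would enter both comparisons alike and could by itself give such agreement. The 1019 transcripts that fell on hnRNP L knockdown had a median log2 fold change of −0.43 there and of −0.277 in UPF1-depleted cells. The latter had an SD of 0.015 over the 3 double-knockdown libraries, each set against the same UPF1 knockdown mean. Sets of equal size matched on mean expression had medians of −0.052 to 0.006, and 88% of the 1019 kept their direction. The 978 that rose had medians of 0.342 and 0.22 (SD 0.024), with matched sets at −0.019 to 0.03, and 92% kept their direction.

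**Figure D4:**
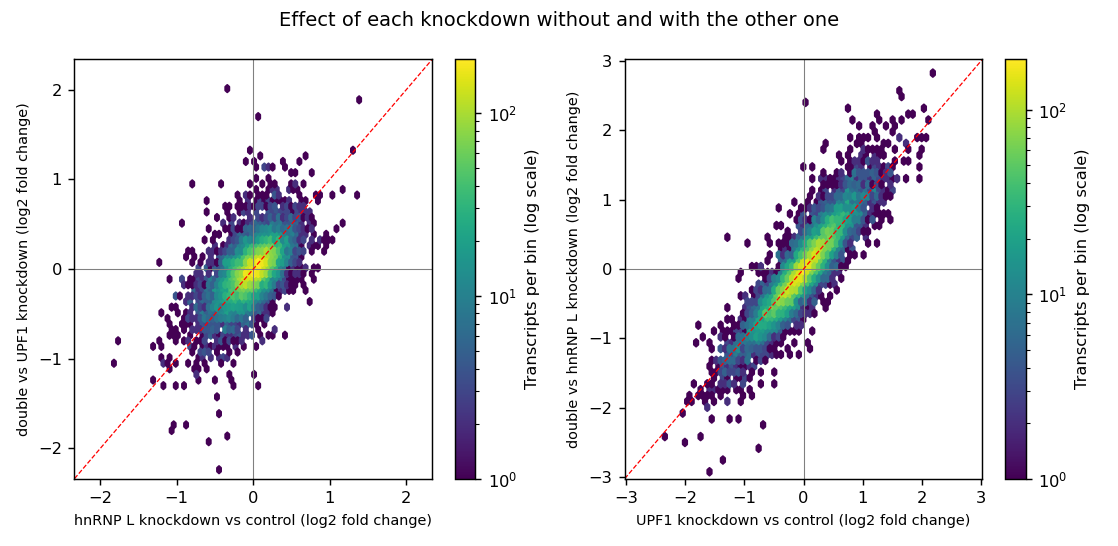
Density of transcripts (colour, log scale, transcripts per bin) by log2 fold change without and with the other knockdown, for hnRNP L (left) and UPF1 (right), with the line of equal effects dashed in red. Fold changes correlated across transcripts at r = 0.597 for hnRNP L and 0.904 for UPF1.

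UPF1 loss in hnRNP L-depleted cells, the double against the hnRNP L knockdown, raised 3141 transcripts and lowered 3131. A fit with the replicate number as a block called 6759, against 6272 without it. ADI1 rose 7.1-fold, DNAH17 5.98-fold, FCGRT 5.31-fold, ZNF528 5.1-fold and RPS27L 5.07-fold. INPP5D, the transcript with the strongest fall on hnRNP L knockdown, rose 5.5-fold from 71.7 ± 26.6 to 406 ± 11.3 normalized counts (log2 fold change 2.46, SE 0.17, adjusted p = 1.91e-08, edgeR). Its level in UPF1-depleted cells was 839 ± 73.8. SYT11 fell 7.59-fold and RAB39B 6.56-fold, and SLC4A8, TUBB3, SFXN3 and FGFR4 fell 5.24- to 6.04-fold. BCL2 rose by 0.37 (SE 0.10, adjusted p = 0.00516) and HNRNPLL by 0.49. Fold changes correlated with those of UPF1 knockdown alone at r = 0.904, and 2513 and 2359 transcripts were higher or lower in both, against 900 and 810.6 for independent lists.

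Among the gene lists, 6 were higher and 4 were lower in this comparison. Of 26 p53 targets, 23 rose and 0 fell (camera adjusted p = 6.39e-08, and adjusted p = 0.0174 with an estimated correlation), with TNFRSF10B at 1.22 and POLH at 0.92. S-phase genes fell in 21 of 28 cases and rose in 1, GINS4 (adjusted p = 2.6e-05, and adjusted p = 0.0174 with an estimated correlation), with MCM3 at −0.80 and MCM4 at −0.84. BCL2 family genes rose in 8 of 15 cases and fell in 2, BAD and BCL2L11 (adjusted p = 0.0315, and adjusted p = 0.115 with an estimated correlation). HRK rose by 1.27 and BCL2L13 by 0.82. NMD reporters (12 rose and 0 fell, adjusted p = 0.000109), NMD factors (7 and 0, 0.00535), stress response genes (17 and 4, 0.000168) and unfolded protein response genes (12 and 1, 0.0294) were higher. Heat shock (2 and 9, 6.17e-05), glycolytic (1 and 10, 0.0103) and oxidative phosphorylation genes (4 and 23, 0.0112) were lower. With an estimated correlation the adjusted p of these 7 was 0.0773, 0.0605, 0.285, 0.144, 0.0605, 0.299 and 0.627. Adjusted over the list alone, 2 S-phase genes, 9 BCL2 family genes and 2 oxidative phosphorylation genes rose, and the other counts were the same. RPKM-implied totals moved the share of higher calls from 50.1% to 61.7% and the median of the oxidative phosphorylation list from −0.102 to −0.011.

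Whether transcripts that fell on hnRNP L knockdown were restored by UPF1 loss was compared between classes. Of the 1019 that fell, 38.6% were higher and 28.2% lower in the double than in the hnRNP L knockdown. Of the 978 that rose, 37.9% were higher and 30.2% lower. Of the 8455 transcripts not called, 28.1% were higher and 30.1% lower. Both classes were selected on the hnRNP L libraries that serve as the baseline here, which alone shifts transcripts that fell towards higher and those that rose towards lower values. The uncalled class and the matched sets are not selected in this way and give no level for that shift. The median change was 0.07 for transcripts that fell (matched sets −0.064 to 0.065) and 0.041 for those that rose (−0.074 to 0.042). The authors' deposited table marks 374 of 1059 transcripts that fell (35.3%) as rescued. The same test in the authors' deposited table was passed by 395 of 1144 that rose (34.5%) and by 2486 of the 8249 others (30.1%). Log2 fold changes in the authors' deposited table correlated with those from edgeR at 0.9996 to 0.9999.

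The single knockdowns were also set side by side. Both raised 460 transcripts and both lowered 365, against 280.2 and 263.8 for independent lists. Opposite calls numbered 188 higher on hnRNP L and lower on UPF1 knockdown (253.2) and 263 the other way (292). Because both comparisons use the same control libraries, simulated unchanged groups gave a correlation of 0.515, a covariance of 0.00746 and 0 shared calls over 10 simulations. The observed values were 0.175 and 0.0212. Part of the excess of shared calls may come from the shared controls, which are too few to split.

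The interaction, the change in the double knockdown beyond the sum of both single log2 changes, passed in 203 transcripts (140 above and 63 below the sum). FCGRT exceeded the sum by 2.34 (SE 0.21, adjusted p = 5.48e-05, edgeR), since its mean was 69.4 in control, 55.7 in hnRNP L-depleted, 72.8 in UPF1-depleted and 296 normalized counts in doubly depleted cells. RPS27L exceeded the sum by 1.60 (SE 0.17, adjusted p = 0.000207), NOV, a matricellular protein gene, by 1.39 and MDFIC by 1.38. SLC4A8 lay below the sum with an interaction of −1.81 (SE 0.15, adjusted p = 1.93e-05), PCP4L1 with −1.5, RAB39B with −1.35 and SYT11 with −1.34. LAMC1, a laminin gene, changed by −0.41 on UPF1 knockdown and by 0.77 in the double knockdown, with an interaction of 1.27 (SE 0.074, adjusted p = 3.24e-07). Sterol genes lay above the sum, with a median of 0.15 (camera adjusted p = 2.68e-06, and adjusted p = 0.00924 with an estimated correlation). INSIG1 passed with 0.99 and HMGCS1 with 0.88, and 3 of 21 sterol genes passed adjusted over the list alone. The p53 targets had a median of 0.21 (adjusted p = 0.000122, and adjusted p = 0.107 with an estimated correlation), or 0.12 without replicate 2 of the UPF1 knockdown. BTG2 passed with 0.48 and POLH with 0.41, and 4 of 26 passed adjusted over the list alone. S-phase genes had a median of −0.12 with 0 members past the threshold over all transcripts and 2 adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.107 with an estimated correlation). The interactions of HNRNPLL (0.02, SE 0.096, adjusted p = 0.965) and BCL2 (0.33, SE 0.14, adjusted p = 0.307) did not pass. The count was 688 without replicate 2 of the UPF1 knockdown and 94 to 135 without any one of 10 other libraries, the exception being replicate 1 of the UPF1 knockdown (161). With a GC correction the count was 972, of which 58.8% lay above the sum against 69%, and with RPKM-implied totals it was 102. With a latent factor as a covariate it was 1570, with about as many above as below the sum.

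Transcripts with long 3′ untranslated regions (UTRs) were more often higher after UPF1 loss, less so with a GC correction. On UPF1 knockdown 37.7% of transcripts in the longest quartile (2336 to 17874 nt) rose and 19.8% fell. In the shortest quartile (16 to 476 nt) 19.8% rose and 31.9% fell. Spearman's rho between 3′ UTR length and fold change across 10452 transcripts was 0.168 for UPF1 knockdown (SD 0.13 over its 3 libraries), 0.126 for the double knockdown and 0.16 for the double against the hnRNP L knockdown. These values were 0.075, 0.045 and 0.087 with a GC correction, and 0.074 for UPF1 knockdown without its replicate 2. For UPF1 knockdown 0.075 and 0.074 lie within the spread over its libraries. With the GC correction its median log2 fold change went from 0.102 to 0.033 in the longest quartile and from −0.078 to −0.041 in the shortest. For hnRNP L knockdown rho was −0.048, within the spread over its 3 libraries (SD 0.072), and it was −0.078 with a GC correction and −0.089 as a partial rho with GC content held fixed. In the longest quartile 10% rose and 12.6% fell on hnRNP L knockdown, and in the shortest 8% rose and 7% fell. In UPF1-depleted cells it was −0.021 and turned to 0.153 without replicate 2 of the UPF1 knockdown. The share of the first 400 nt after the stop codon covered by CA motifs, over 6303 transcripts, correlated with fold change at −0.042 for hnRNP L knockdown (SD 0.011 over its 3 libraries), 0.024 for UPF1 knockdown (SD 0.0014) and −0.026 in the double against the UPF1 knockdown (SD 0.01). These SDs, like those for 3′ UTR length, set each knockdown library against the same baseline mean. They leave out the spread between baseline libraries and so understate the uncertainty of a rho. With GC content and 3′ UTR length held fixed, the partial rho in these comparisons was −0.025, 0.028 and −0.019. On hnRNP L knockdown 9.6% of 633 CA-rich transcripts and 8.9% of 2732 transcripts without a motif fell. In UPF1-depleted cells the shares that fell were 12.6% and 9.1%.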

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

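The test of GC content on the within-group axis, the split of deviations by library, and the choice of replicate 2 of the UPF1 knockdown as the library to leave out, were made after that axis had been seen. The other tests here were written down before their results, but without the margin of an SE that was used for list medians.

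The effect of hnRNP L knockdown differed between cells with and without UPF1 in 203 transcripts by the test of the interaction (edgeR). Among the strongest were FCGRT (2.34 on the log2 scale), RPS27L (1.60), NOV (1.39) and MDFIC (1.38), above the sum of both single changes. SLC4A8 (−1.81), PCP4L1 (−1.5), RAB39B (−1.35) and SYT11 (−1.34) lay below it. As lists, p53 targets (median 0.21), sterol genes (0.15) and S-phase genes (−0.12) differed at the preset correlation. With an estimated correlation the sterol genes kept their call (adjusted p = 0.00924), and the p53 targets and S-phase genes did not (adjusted p = 0.107 for both). Of 100 drawn splits of the 12 libraries, 2 gave at least as many transcripts, the real one included. Drawn groups mix UPF1-depleted with other libraries, which widens the spread within groups and leaves few calls. The share of splits therefore cannot decide whether 203 interactions exceed what unrelated libraries would give. The other of these 2 splits called 3262 transcripts. It placed 5 of the 6 UPF1-depleted libraries on one side and so follows UPF1 status, which is a structure of the samples. The next highest split called 6, and 94 splits called 0.

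Libraries of a group deviated from each other mainly along 1 axis, which held 54.2% of the within-group variance and on which replicate 2 of the UPF1 knockdown scored 0.70. Depth is argued against, because the axis still held 50.2% after every library was thinned to 6594833 reads. Transcript length is argued against as well, with a partial rho of 0.169 once GC content was held fixed. GC content remains a candidate explanation for part of the axis, since the loadings followed it with a rho of −0.837, and a GC correction brought the axis to 29.5% and the within-group variance to 61.9% of its former size. That library held 28.1% of the within-group variance before and 17.6% after the correction, which left 38.8% of its own squared deviation, and no biological explanation was tested.

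Sterol genes differed in their response to hnRNP L knockdown with and without UPF1. A GC trend as the whole source is argued against, because the median interaction stayed at 0.15 (SE 0.042, adjusted p = 1.79e-06) with the GC correction. The divergent UPF1 knockdown library is argued against, because the median was 0.17 (SE 0.047, adjusted p = 3.12e-06) without it. A batch that shifts both hnRNP L-depleted groups alike cancels in the interaction. The list had a median of −0.086 on hnRNP L knockdown alone (adjusted p = 0.503, and 0.635 with an estimated correlation) and 0.051 in UPF1-depleted cells (0.0036 and 0.0976), so it was called only in the latter and only at the preset correlation, and an effect of the knockdowns as the source stays open, not tested in other cultures.

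The p53 targets fell as a list on hnRNP L knockdown alone and had a median interaction of 0.21, both at the preset correlation only (adjusted p = 0.17 and 0.107 with an estimated correlation). A GC trend is argued against, as the median stayed at 0.21 (SE 0.044, adjusted p = 9.74e-06) with the GC correction. Without replicate 2 of the UPF1 knockdown it was 0.12 (SE 0.033, adjusted p = 0.000382). The written rule for arguing against this library, a median at 50% or more of the full one and a list past the threshold, was met. The value less its SE lies under 50%, a margin that was not part of that rule. It is thus too close to exclude that this library supplied much of the pattern. The library and an effect of the knockdowns cannot be told apart here.

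The 5 comparisons of 3 libraries against 3 allow only 10 splits each, of which 1, the real one, gave as many transcripts. Such a design cannot reach a share under 0.05. The real counts were 1997, 5701, 6635, 2004 and 6272, and the highest of the other splits called 0 in each. Every other split mixes the groups compared, which widens the spread within groups. The 0 calls there are thus no evidence on the real counts.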

How the results depend on the processing

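The GC correction, the latent factor and RPKM-implied totals were added after seeing the data. So were the values without replicate 2 of the UPF1 knockdown for lists, correlations and comparisons that do not use it. Blocked fits of lists or with a GC correction were added then as well. The causes of the differences below were not tested, except where fewer libraries or a stricter threshold make them.

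Counts of transcripts for UPF1 knockdown, the double knockdown and the double against the hnRNP L knockdown stayed within 1.5 times under every alternative except a minimum fold change. At 1.5-fold they were 2000, 2871 and 2581, and at 2-fold 492, 998 and 782. For hnRNP L knockdown, the double against the UPF1 knockdown and the interaction, a 1.5-fold minimum left 360, 427 and 128, and a 2-fold minimum 39, 63 and 31. An adjusted p of 0.01 left 900, 998 and 58, and one of 0.1 gave 351 for the interaction. A GC correction gave 3611, 3696 and 972, a latent factor 4330, 4466 and 1570, and RPKM-implied totals 1239, 1312 and 102. With only the groups compared the first 2 were 3241 and 956. The latent factor is estimated from the residuals and so lowers them by construction. Called transcripts changed sign only under the GC correction, in 11, 46 and 12 cases for UPF1, double and double against hnRNP L knockdown.

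Leaving out each library of the groups compared gave 1112 to 1469 transcripts for hnRNP L knockdown, 4940 to 6132 for UPF1 knockdown, 5973 to 6197 for the double knockdown, 1330 to 3141 for the double against the UPF1 and 5618 to 5892 for the double against the hnRNP L knockdown. The interaction ranged from 94, without replicate 2 of the hnRNP L knockdown, to 688, without replicate 2 of the UPF1 knockdown. The lowest values for hnRNP L knockdown and for the double against the UPF1 knockdown came without hnRNP L replicate 3 and without double replicate 1, and the highest of the latter (3141) without UPF1 replicate 2. Comparisons that do not use that library gave 3305 for hnRNP L knockdown, 7408 for the double knockdown and 7165 for the double against the hnRNP L knockdown without it.

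The replicate numbers were taken as a possible pairing only in the double against each single knockdown, and the main fit did not use them. Over all groups, 11 of 18 same-numbered pairs had deviations correlated above 0.1 (−0.46 to 0.54). As a hint from the data, 9 of 12 libraries correlated best with their own number. With the replicate number as a block the counts were 2541, 6149, 7019, 2575, 6759 and 341 in the order of the report, the last being the interaction. In the double against each single knockdown the block changed no call of a list or of a gene named for the size of its change, with 5 (against UPF1) and 10 lists (against hnRNP L) past the threshold. With the block and a GC correction, 3980 and 7394 transcripts and 5 and 12 lists passed, in the same order.

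Lists past the threshold with an estimated correlation numbered 0 for hnRNP L, 3 for UPF1 and 0 for double knockdown, 0 and 2 for the double against UPF1 and hnRNP L knockdown, and 1 for the interaction. A preset correlation of 0.05 left 3 for the double knockdown, 0 for the double against UPF1 and 6 for the double against hnRNP L knockdown. For the double against UPF1 knockdown a background with a mean of at least 100 left 3, and leaving out UPF1 replicate 2 left 1. Over all comparisons, 41 list calls ended with the estimated correlation, 23 with the preset of 0.05, 12 when fold changes alone were ranked (cameraPR), 4 with that background, 1 with a GC correction and 5 without UPF1 replicate 2.

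At an adjusted p of 0.01, calls shared in direction were 364 for hnRNP L knockdown with and without UPF1 and 324 for the single knockdowns. Transcripts that fell then had a median of −0.331 in UPF1-depleted cells (−0.261 at a mean of at least 100), and those that rose 0.273. Spearman's correlation of fold change with 3′ UTR length was 0.045 for double and 0.087 for double against hnRNP L knockdown with a GC correction, and for double against UPF1 knockdown it turned to 0.153 without UPF1 replicate 2. The correlation with CA motifs on UPF1 knockdown was 0.027 (GC) and 0.022 (without that library).

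Among genes named for the size of their change no call was lost under any of these settings that refit the model. BCL2, not called on UPF1 knockdown, had 0.05 there, 0.15 with RPKM-implied totals and 0.11 without control replicate 1, and turned to −0.03 with a GC correction and −0.01 without control replicate 3. It passed in the double knockdown with a GC correction (−0.29, adjusted p = 0.0071) or a latent factor (−0.22, 0.0251), and against UPF1 knockdown (−0.25, 0.0276, and −0.27, 0.0119, or −0.26, 0.0269 with block and GC correction). The interaction of HNRNPLL, not called, turned to 0.00 without control replicate 1, −0.01 without UPF1 replicate 3 and −0.03 without double replicate 1. Tests fixed for normalized values or the authors' comparisons alone did not apply and were not run, nor was that of the targeted genes, and leaving out the low-count filter changed nothing. In simulated data 20 of 50 changes of 1.3-fold were found on hnRNP L knockdown. Responses of that size or smaller can thus be missed at this depth and number of libraries. That simulation left 10252 of 10452 transcripts unchanged, whereas 1997 were called on hnRNP L knockdown in the data. The adjusted p depends on how many transcripts change, so the simulated recovery does not give the share missed in the data.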

Other observations

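The comparison of opposing interactions below, its test and its genes were chosen after seeing the data. The tests of CA motifs, of 3′ UTR length and of held-out libraries were written down before their results.

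Gene lists without a call by camera also held single genes that moved. On UPF1 knockdown the exon junction complex genes were split, with RBM8A up by 0.91 and RNPS1, a peripheral component, down by 0.83 on the log2 scale (3 rose and 5 fell of 11, camera adjusted p = 0.585). SR protein genes were split as well, with SRSF5 up by 0.62 and SRSF4 down by 0.57 (6 rose and 3 fell of 13, adjusted p = 0.856). Of 25 other hnRNP genes, 6 rose and 7 fell (adjusted p = 0.977), and HNRNPDL rose by 0.47. Of 33 decay enzymes, 10 rose and 7 fell (adjusted p = 0.925), among them the decapping cofactor gene PNRC2, up by 0.62, and the deadenylase gene CNOT8, down by 0.55. In the double knockdown DCP2, encoding the decapping enzyme, rose by 0.87. Mitotic genes fell in 15 of 28 cases and rose in 5 on UPF1 knockdown without a call for the list (adjusted p = 0.199). KIF20A and CDK1 fell by 0.47 and 0.42, and BIRC5 rose by 0.52. Within each list alone the adjusted counts were the same except 6 mitotic genes that rose. By fry the exon junction complex and mitotic genes passed on UPF1 knockdown (adjusted p = 0.00389 and 0.0204). The SR protein, hnRNP and decay enzyme genes did not (fry adjusted p = 0.214, 0.703 and 0.17).

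Of 32 interferon-stimulated genes, which transfected RNA can induce, 15 were measured, and these did not move as a list. Genes with fewer than 25 counts in any control library are missing, so induction from a silent state could not be seen. On UPF1 knockdown 5 of 15 rose and 4 fell (camera adjusted p = 0.916), with IFI44L up by 1.24 and STAT2 down by 0.60, and on hnRNP L knockdown 0 rose and 0 fell (adjusted p = 0.89). Immediate early genes gave 2 that rose and 5 that fell of 13 on UPF1 knockdown (adjusted p = 0.75), among them JUN, up by 0.72, and NR4A1, down by 0.89. On hnRNP L knockdown EGR1 fell by 0.75 and DUSP6 by 0.45. With adjustment over the list alone, the interferon counts were the same and 3 immediate early genes rose and 6 fell on UPF1 knockdown. Of the marker lists for other cell types, 1 of 21 blood cell markers and 3 of 18 markers of other tissues were measured, too few to test.

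One hypothesis was that falls on hnRNP L knockdown depend on UPF1, in which case they should shrink in UPF1-depleted cells more than rises do. Transcripts were selected on 2 control and 2 hnRNP L libraries and measured on the held-out ones, over 9 hold-outs. The change in UPF1-depleted cells was 0.71 of the held-out change for falls (SD 0.094 over hold-outs, which share libraries) and 0.72 for rises (SD 0.095), a difference of −0.01 (SD 0.018). All 9 hold-outs used the same double and UPF1 knockdown libraries, so these SDs leave out the spread between those libraries. The falls thus shrank no more than the rises did. For the falls as a class this argues against dependence on UPF1 only as far as UPF1 was depleted, which was not checked. It also holds only as far as the falls come from the knockdown and not from a batch that coincides with it. The values do not exclude dependence for a minority.

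Such a minority was looked for among single interactions. An interaction opposing the hnRNP L effect passed for 57 of 1019 transcripts that fell (5.6%) and 22 of 978 that rose (2.2%, Fisher's exact test, two-sided p = 0.000126). An interaction adding to the effect passed for 9 and 12. The classes and the interaction use the same control and hnRNP L libraries, so more opposing than adding interactions are expected from the selection alone, and no held-out libraries were used here. Transcripts are not independent, and interactions were more often above than below the sum overall (140 against 63, but 788 against 782 with a latent factor as a covariate), so this difference is a description. The same exact test gave 209 against 128 with a GC correction (Fisher's exact p = 9.38e-06) and 146 against 72 without replicate 2 of the UPF1 knockdown (Fisher's exact p = 6.12e-07). GNPDA1 fell by 0.40 on hnRNP L knockdown and rose by 0.51 in UPF1-depleted cells (interaction 0.91, SE 0.10, adjusted p = 0.000337, edgeR). PIK3R3, STX3, LAMP1 and CSF1 had interactions of 0.83, 0.90, 0.83 and 1.27. FARP1 fell in both settings, by 1.75 and 0.78 (interaction 0.98, SE 0.14, adjusted p = 0.00181). GALNT4 passed too, but it overlaps the read-through gene POC1B-GALNT4 and may share its reads, which leaves it uncertain.

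Whether these 57 transcripts carry features of hnRNP L-protected NMD targets could not be settled. Their median 3′ UTR length was 1560 nt against 1410 nt for the other transcripts that fell (one-sided permutation p = 0.287). CA motif cover after the stop codon had a median of 1.25% in both classes (one-sided permutation p = 0.936). It was thus no higher, which is the outcome written down against CA motifs as a mark of these falls. This test cannot decide the question, since 2732 of the 6303 transcripts read had no motif, which makes a median of cover coarse. Most random draws gave a difference of medians at least as high. No conclusion on CA motifs is therefore drawn from it. A value existed for 35 of the 57 (61.4%) and for 609 of the 962 others, so these medians describe only transcripts with a value. A test with more replicates and with annotated binding sites of hnRNP L would bear on this hypothesis, which may hold for few transcripts.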
